A study of Mus musculus with 12 samples.

How the data were processed

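RNA from the hearts of male mice of the C57Bl/6J strain, 12 weeks old, was compared in 4 groups of 3 libraries. The labels give each library its diet, its surgery and its replicate number. Per the labels' protocols, total RNA was extracted with Trizol and polyadenylated RNA was selected; no library kit is named. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2 and DESeq2 were used with the mouse genome build GRCm38 (mm10). What each tool did, its settings and whether reads were counted by strand are not given in the sources used here. A gene that overlaps another gene, an antisense gene or a near-identical copy may therefore share reads with it, and values of such genes are uncertain.

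The authors deposited 4 tables, 1 for each pair of groups that differ in diet or in surgery alone. The deposited library columns hold a signal that is never negative, the reads of a gene divided by a size factor of the library, as the values show. The deposited fold change column holds log2 values of the authors' comparison, per the file headers. The authors' p-value and adjusted p-value stand beside it, per the file headers. The authors made size factors separately for each table: 1 unit stood for 0.822 reads of control sham replicate 1 in its first table and for 0.861 in its second. All per-sample columns were matched to a library by its label. The tables list 15928, 15960, 15613 and 16234 genes, with a lowest mean of 9.03 to 9.77 per table, so genes of lower expression are not analysed here. The authors' p-value was missing for 76, 4, 5 and 74 genes and the adjusted p-value for 384, 4, 5 and 1011 genes, in the order TAC on the control diet, TAC on the BCAA-free diet, diet in sham hearts and diet in TAC hearts; these stayed missing.

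Whole reads were recovered by dividing each column by the value of 1 read. At a tolerance of 0.001 reads, 100% of the values came out whole, and for the 15414 to 15822 genes found in both tables of a library 0 had different reads. Recovered reads per library ranged from 29925880 to 46092728, and 15665 genes had reads in all 12 libraries. Reads are not independent molecules here, since no molecular identifiers are stated, so intervals on counts cover counting error only. Of 16514 gene identifiers, 16475 were found in the GENCODE M21 annotation of GRCm38, which gave the coordinates.

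Which test to use for raw counts and which for normalized values was written before the data were examined, as were the comparisons, the gene lists, the rule for named genes and the alternatives, except where an alternative is said to be added later. The values proved to be normalized, so the main test was limma 3.58.1 with an intensity trend on log2(value + 4), in R 4.3.3, for genes with a mean of at least 10 in the libraries compared. Fold changes are on that scale, which understates the change of low genes. Each of the 4 pairwise comparisons was tested within its own table. The difference of the TAC responses between diets used the 12 columns of both TAC tables, and the diet effect averaged over surgery used the 12 columns of both diet tables, so that each difference was taken within 1 table. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and the number that also changed at least 2-fold was counted. The size of the TAC response on the diets was compared over genes past the threshold for the mean TAC effect, as the percent of genes whose change was smaller on the BCAA-free diet, with a 95% exact binomial interval that treats genes as independent, which they are not.

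The 41 gene lists cover cardiac stress and contraction, extracellular matrix, fuel metabolism, amino acid and propionate handling, protein synthesis and turnover, stress responses, the clock, the cell cycle, interferon response, chromatin acylation and markers of cell types that a heart sample could hold. Lists were tested with camera at a preset correlation between genes of 0.01 where at least 5 members were tested, adjusted over the lists; 39 were tested, and the lists of lung and of thymus markers had too few members in each comparison. With an estimated correlation, camera called 0 lists in every comparison, with 2 to 5 at an unadjusted p under 0.05 and 0 to 6 called by fry, so each list call rests on the preset value, with which camera also takes more degrees of freedom. The test fry, which asks whether a list moves one way on balance and compares it with no other gene, was also run. The median of every list that passed had the same sign as its test.

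Named genes follow a fixed rule. In each comparison they are the 6 with the largest rise and the 6 with the largest fall among genes past the threshold, with a mean of at least 50, a symbol that is not a predicted gene and, in the pairwise comparisons, groups that do not overlap. The rule adds up to 2 members of each described list with the smallest p among those past the threshold, or the 1 smallest as values where none passed. Nppa, Nppb, Myh7, Acta1, Myh6, Atp2a2, Col1a1 and Postn are added everywhere as a check of the labels. The text leaves out some of these genes.

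Alternatives were pseudocounts of 1 and 16, no filter or a mean of at least 50, quantile normalization, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, edgeR on all 12 libraries in 1 fit, the authors' own calls, and leaving out each library in turn. Where that left 2 libraries in a group, limma pooled the spread over groups. Leaving out control TAC replicates 2 and 3 together, which leaves 1 control TAC library that is assumed to vary like the others, was added after seeing the data.

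Whether replicate numbers pair libraries was checked as the correlation, across genes, of deviations from group means. In the diet comparison of sham hearts, same-numbered libraries correlated at 0.105 to 0.353 and others at -0.233 to 0.123. All 3 pairs lay above the limit of 0.1 set beforehand, so the blocked fit is given beside the main result there. The labels name no shared litter, day or batch, and the counts of both fits had been computed by then. In the other comparisons the numbers are not treated as pairs.

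The scripts were tested on simulated reads with 200 changed genes per comparison. At the same sizes limma called 144 genes for TAC on the control diet (7.64% false), 163 for TAC on the BCAA-free diet (7.36% false), 172 for diet in sham hearts (8.14% false) and 134 for diet in TAC hearts (8.96% false). It called 115 for the difference of TAC responses (6.09% false) and 182 for the averaged diet effect (5.49% false). A 2-fold change was recovered in 70.1%, 82.1%, 80.6%, 58.2%, 52.2% and 88.1% of cases in the same order. On the simulated control diet comparison, 1 of 1 raised list and 0 of 20 unchanged lists were called. The simulated genes were drawn independently of each other. How often camera calls an unchanged list of correlated genes was therefore not tested by it. Every real split into groups was also set against other splits of the same libraries.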

Results

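Gene expression was measured in whole hearts of mice that ate either a diet with the branched-chain amino acids (BCAA, which are leucine, isoleucine and valine) or a diet without them. Both diets contained 1% propionate, a short-chain fatty acid that cells convert to propionyl-CoA, which the breakdown of isoleucine and valine also yields. Feeding began 4 days before sham surgery or transverse aortic constriction (TAC), a narrowing of the aorta that loads the left ventricle with pressure. The hearts were taken 1 week after surgery. The groups are called control sham, control TAC, BCAA-free sham and BCAA-free TAC, each with n = 3 libraries that held 29925880 to 46092728 reads assigned to genes. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. Levels are normalised reads with their SD, and levels of different tables were normalised separately. Changes are log2 differences with their SE, and adjusted p-values come from limma unless another tool is named. Each library was also left out in turn. Other groupings of the libraries called at least as many lists in every comparison, so list calls leave chance open.

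Some transcripts set 2 control TAC libraries apart from the rest. Control TAC replicate 3 held 559 CPM (95% exact binomial interval 552 to 566) over 34 liver transcripts, against 18.1 to 44.6 CPM in the other 5 control diet libraries. Alb, which encodes serum albumin, had 6668 reads there and 0 to 3 reads in the other libraries in which it was listed. Control TAC replicate 2 held 122 CPM of Rn7sk, Rmrp and Rpph1, which are non-coding RNAs made by RNA polymerase III, against 1.59 to 26.3 CPM in the other 11 libraries. Counts that rest on control TAC hearts are therefore also given without both of these libraries, a choice made after seeing the data.

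**Figure D1:**
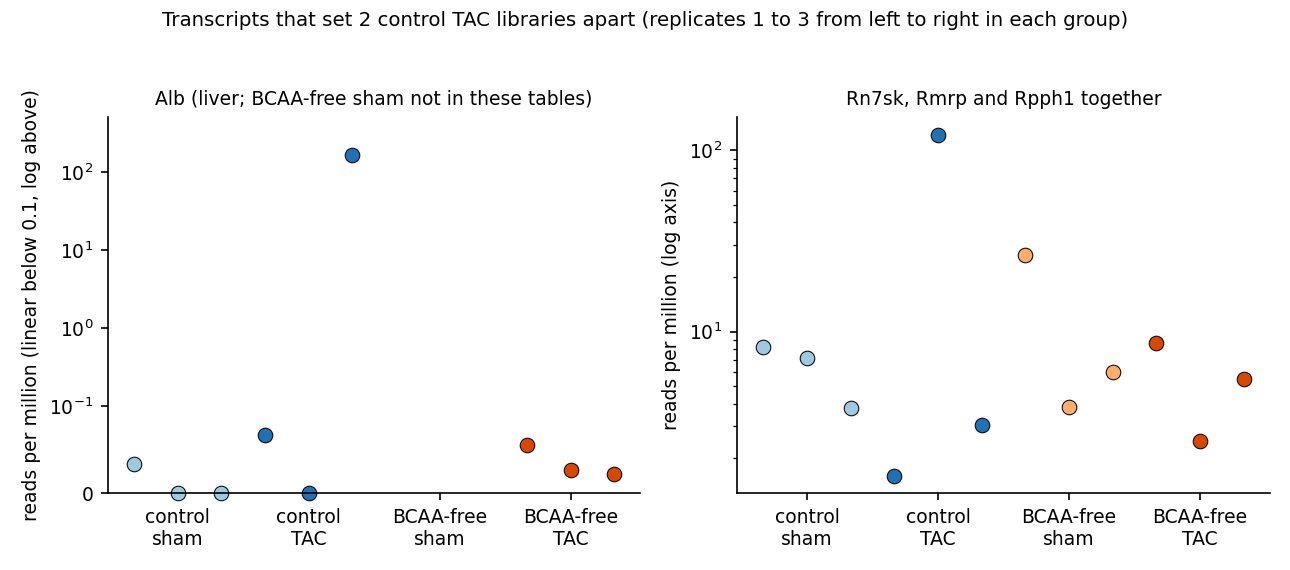
Level in CPM (vertical axes, on the left linear below 0.1 and logarithmic above, on the right logarithmic) of Alb, without BCAA-free sham, and of the 3 RNA polymerase III transcripts Rn7sk, Rmrp and Rpph1 together, with 1 point per library in each group. Control TAC replicate 3 had 6668 Alb reads and control TAC replicate 2 had 122 CPM of the 3 transcripts, above the other libraries plotted.

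The first comparison asked what pressure overload changed in hearts on the control diet. Genes of cardiac stress, scar matrix and cell division were among those that rose, and genes of fat burning among those that fell. Igfbp2, which binds insulin-like growth factors, rose 21.6-fold (log2 4.43 ± 0.26, n = 3 per group, adjusted p = 0.000121), from 4.48 ± 0.806 to 183 ± 49.6 normalised reads. Acta1, the skeletal muscle actin that stressed heart muscle makes again, rose 6.09-fold (2.61 ± 0.09, adjusted p = 1.56e-06). Postn, a matrix protein of activated fibroblasts, rose 4.79-fold (2.26 ± 0.29, adjusted p = 0.00551), and Ucp3, a mitochondrial carrier linked to fatty acid use, fell (-1.40 ± 0.16, adjusted p = 0.00378). On GRCm38, Igfbp2 (ENSMUSG00000039323, chromosome 1 from 72824503 to 72852474) and Acta1 (ENSMUSG00000031972, chromosome 8 from 123891769 to 123894751) are protein-coding genes. In all, 540 genes rose and 308 fell of 15873 tested, 213 and 24 of them at least 2-fold. The count of 848 was 305, 660 and 338 without control sham replicates 1, 2 and 3, and 402, 400 and 91 without control TAC replicates 1, 2 and 3. Without both control TAC replicates 2 and 3 it was 180, with 138 up and 42 down (3097 at an unadjusted p under 0.05, and 958 by edgeR), and 130 of these were among the 848. Ucp3 (adjusted p = 0.056) did not pass with control TAC replicates 2 and 3 both left out.

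Cell cycle genes had the largest list median, with 24 of 26 that rose (25 adjusted over the list alone, median 1.94, camera adjusted p = 3.79e-26, adjusted p = 0.487 with an estimated correlation). Examples were Ccna2, a cyclin of S phase and mitosis (2.42 ± 0.23, adjusted p = 0.0022), Aurkb, a mitotic kinase (2.57 ± 0.25, adjusted p = 0.00235), and the proliferation marker Mki67 (2.76 ± 0.42, adjusted p = 0.0101). Mki67 did not pass with control TAC replicate 3 left out (adjusted p = 0.0767). Without both control TAC replicates 2 and 3 the list median was 2.02 (camera adjusted p = 8.2e-14), with 0 of 26 members past the threshold. Ccna2 (adjusted p = 0.0586), Aurkb (adjusted p = 0.071) and Mki67 (adjusted p = 0.162) did not pass with control TAC replicates 2 and 3 both left out.

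Scar matrix genes rose together, with 28 of 42 of their list past the threshold (39 adjusted over the list alone, median 1.08, camera adjusted p = 1.13e-26, adjusted p = 0.593 with an estimated correlation). Cilp rose by 1.54 ± 0.17, the proteoglycan gene Bgn by 0.86 ± 0.11, and Tnc and Cthrc1, matrix genes of wound healing, by 3.13 ± 0.59 and 3.22 ± 0.62. In the fetal and hypertrophy list 7 of 15 rose (11 adjusted over the list alone, median 0.63, camera adjusted p = 1.02e-08, adjusted p = 0.609 with an estimated correlation), including Xirp2, an actin-binding protein of heart muscle (1.05 ± 0.15). The natriuretic peptide gene Nppb (1.55 ± 0.32), Myh7, the slow myosin heavy chain (0.63 ± 0.12), and the collagen gene Col1a1 (1.53 ± 0.29) rose too. Nppa did not pass (1.32 ± 0.33, adjusted p = 0.0541), nor did the myosin gene Myh6 (-0.06, adjusted p = 0.87) or the calcium pump gene Atp2a2 (-0.31, adjusted p = 0.185), which passed by DESeq2 (0.00283). Tnc, Myh7 and Col1a1 did not pass with control sham replicate 1 or 3 or control TAC replicate 3 left out (adjusted p = 0.0542 to 0.0823), nor did Nppb with control sham replicate 3 or any 1 control TAC library (0.0677 to 0.0918). Cthrc1 did not pass with any 1 control sham library or control TAC replicate 3 left out (adjusted p = 0.0506 to 0.0734). Nppb (adjusted p = 0.181) did not pass with control TAC replicates 2 and 3 both left out.

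By camera, lists of fat and BCAA breakdown and of mitochondrial respiration fell. In the fatty acid list 12 of 34 fell (26 adjusted over the list alone, median -0.34, camera adjusted p = 7.06e-17, adjusted p = 0.535 with an estimated correlation), among them Lipe, which encodes hormone-sensitive lipase (-0.49 ± 0.06, adjusted p = 0.00539). The nuclear respiratory chain list had 6 of 46 that fell (13 adjusted over the list alone, median -0.18, camera adjusted p = 4.23e-11, adjusted p = 0.685 with an estimated correlation), for example Cox7a1 (-0.73 ± 0.14). BCAA catabolism genes fell as a list, 1 of 22 past the threshold (3 adjusted over the list alone, median -0.19, camera adjusted p = 0.000138, adjusted p = 0.685 with an estimated correlation). That gene was Bckdha, of the enzyme complex that commits BCAA to breakdown (-0.58 ± 0.09, adjusted p = 0.0131). The propionate list fell, 3 of 19 past the threshold (11 adjusted over the list alone, median -0.23, camera adjusted p = 0.000135, adjusted p = 0.685 with an estimated correlation). So did the TCA cycle list, 1 of 20 (5 adjusted over the list alone, median -0.12, camera adjusted p = 0.000668, adjusted p = 0.708 with an estimated correlation). Cox7a1 did not pass with control sham replicate 1 or 3 or control TAC replicate 3 left out (adjusted p = 0.0691 to 0.0758), nor did Bckdha with control TAC replicate 3 (0.0724). Lipe (adjusted p = 0.0757) did not pass with control TAC replicates 2 and 3 both left out.

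Targets of ATF4, the regulator of the response to amino acid shortage, rose as a list, in which 6 rose and 1 fell of 30 (11 rose and 1 fell adjusted over the list alone, median 0.23, camera adjusted p = 0.00203, adjusted p = 0.487 with an estimated correlation). It was led by Mthfd2 of mitochondrial folate metabolism (1.89 ± 0.34, adjusted p = 0.0176). Macrophage markers rose as a list, 1 of 22 past the threshold (7 rose and 1 fell adjusted over the list alone, median 0.40, camera adjusted p = 0.000228, adjusted p = 0.708 with an estimated correlation). Their median was 0.15 without control TAC replicate 1 and 0.88 without both replicates 2 and 3 (camera adjusted p = 0.0182 and 1.89e-11). Neutrophil markers fell, 1 of 5 past the threshold (2 adjusted over the list alone, median -0.90, camera adjusted p = 0.0087, adjusted p = 0.685 with an estimated correlation), the calcium-binding protein gene S100a9 (-2.60 ± 0.56, adjusted p = 0.0311). The neutrophil list was not called without both control TAC replicates 2 and 3 (camera adjusted p = 0.564). Mthfd2 did not pass with control sham replicate 3 or control TAC replicate 1 or 3 left out (adjusted p = 0.0596 to 0.0961), nor did S100a9 with control sham replicate 1 or 3 or control TAC replicate 2 or 3 (0.0841 to 0.13). Mthfd2 (adjusted p = 0.148) and S100a9 (adjusted p = 0.316) did not pass with control TAC replicates 2 and 3 both left out. Interferon genes (median 0.14, camera adjusted p = 0.172), fibroblast markers (median 0.23, camera adjusted p = 0.072) and ribosomal protein genes (median 0.02, camera adjusted p = 0.536) did not pass as lists. The fibroblast list did pass, with a positive median, without control sham replicate 1 (0.0379), control TAC replicate 2 (0.0277) or both control TAC replicates 2 and 3 (0.0129) and after quantile normalization (0.0409), as did interferon genes without control sham replicate 2.

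After the same surgery on the BCAA-free diet, scar matrix, macrophage and fibroblast genes were among those that rose. Tnc rose 11.7-fold (log2 3.54 ± 0.29, n = 3 per group, adjusted p = 0.000857). Timp1, an inhibitor of matrix proteases, rose by 2.94 ± 0.26. Igfbp2 rose 12.5-fold (3.64 ± 0.43, adjusted p = 0.00285). Epha4, an ephrin receptor, fell (-1.03 ± 0.09, adjusted p = 0.000857). In total 469 genes rose and 219 fell of 15936 tested, 163 and 9 of them at least 2-fold. This count of 688 was 107, 105 and 119 without BCAA-free sham replicates 1, 2 and 3, and 793, 387 and 1195 without BCAA-free TAC replicates 1, 2 and 3. The 4 genes named here passed whichever library was left out.

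In the extracellular matrix list 32 of 42 rose (39 adjusted over the list alone, median 1.26, camera adjusted p = 2.86e-35, adjusted p = 0.411 with an estimated correlation), Postn among them (2.69 ± 0.39, adjusted p = 0.00626). Macrophage markers rose in 16 of 22 cases (21 adjusted over the list alone, median 0.88, camera adjusted p = 1.49e-22, adjusted p = 0.388 with an estimated correlation). They included Lyz2, a lysozyme (0.87 ± 0.08, adjusted p = 0.00103), and Ctss, a lysosomal protease (1.26 ± 0.12, adjusted p = 0.00125). Fibroblast markers rose in 8 of 14 cases (10 adjusted over the list alone, median 0.49, camera adjusted p = 3.86e-09, adjusted p = 0.388 with an estimated correlation), led by Mfap5 (2.07 ± 0.21), a protein of elastic microfibrils, and Pi16 (1.26 ± 0.15). Interferon genes rose as a list, 3 of 21 past the threshold (9 adjusted over the list alone, median 0.34, camera adjusted p = 1.39e-05, adjusted p = 0.411 with an estimated correlation), among them Ifi27l2a (1.00 ± 0.14, adjusted p = 0.00507). T cell markers fell, 1 of 13 past the threshold (5 adjusted over the list alone, median -1.25, camera adjusted p = 1.63e-05, adjusted p = 0.417 with an estimated correlation), the receptor gene Il7r (-1.17, adjusted p = 0.0256). Il7r did not pass with any 1 BCAA-free sham library or BCAA-free TAC replicate 2 left out (adjusted p = 0.0521 to 0.116).

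Of the fetal and hypertrophy genes 7 of 15 rose (11 adjusted over the list alone, median 0.71, camera adjusted p = 1.21e-09, adjusted p = 0.411 with an estimated correlation). Myh7 rose by 1.12 ± 0.10 (adjusted p = 0.000957), Nppa by 1.95 ± 0.33, Nppb by 1.12 ± 0.27, Acta1 by 1.83 ± 0.37 and Col1a1 by 1.93 ± 0.31. Myh6 (0.03, adjusted p = 0.957) and Atp2a2 (-0.36, adjusted p = 0.186) did not pass, but Atp2a2 did by edgeR (0.0412) and DESeq2 (0.000641). Among ion channel genes 3 of 16 fell (7 adjusted over the list alone, median -0.24, camera adjusted p = 0.00096, adjusted p = 0.388 with an estimated correlation), including Scn4b, a sodium channel subunit (-0.73 ± 0.12). The cell cycle list had 1 of 25 that rose (2 adjusted over the list alone, median 0.26, camera adjusted p = 0.00863, adjusted p = 0.548 with an estimated correlation), Ccna2 (1.35 ± 0.33, adjusted p = 0.0438). Nppa did not pass with BCAA-free sham replicate 2 or 3 left out (adjusted p = 0.0707 and 0.0714), nor did Nppb with any 1 BCAA-free sham library or BCAA-free TAC replicate 2 (0.0841 to 0.172). Acta1 and Col1a1 did not pass with any 1 BCAA-free sham library left out (adjusted p = 0.0544 to 0.121), nor did Scn4b with BCAA-free sham replicate 1 or 2 (0.0541 and 0.0608). Ccna2 did not pass with any 1 BCAA-free sham library or BCAA-free TAC replicate 1 or 3 left out (adjusted p = 0.0742 to 0.169). After quantile normalization Nppb and Ccna2 did not pass (adjusted p = 0.0543 and 0.0543), nor did Nppb by DESeq2 (0.0711). The cell cycle list did not pass with BCAA-free TAC replicate 1 left out (camera adjusted p = 0.224).

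Ribosomal protein genes rose as a list, 1 of 37 past the threshold (6 adjusted over the list alone, median 0.14, camera adjusted p = 2.23e-08, adjusted p = 0.42 with an estimated correlation). Among ATF4 targets, which rose as a list, 3 rose and 1 fell of 30 (8 rose and 2 fell adjusted over the list alone, median 0.14, camera adjusted p = 0.00863, adjusted p = 0.411 with an estimated correlation). Eif4ebp1, a repressor of translation, was 1 of those that rose (0.58 ± 0.06, adjusted p = 0.00195). The fatty acid list fell with 0 of 34 past the threshold (0 adjusted over the list alone, median -0.20, camera adjusted p = 1.09e-06, adjusted p = 0.449 with an estimated correlation), while the respiratory chain list did not pass (median 0.04, camera adjusted p = 0.383). Of the endoplasmic reticulum stress genes 3 of 18 fell (6 adjusted over the list alone, median -0.13, camera adjusted p = 0.000336, adjusted p = 0.45 with an estimated correlation), led by the chaperone gene Hspa5 (-0.59 ± 0.11). BCAA catabolism genes fell as a list, 0 of 22 past the threshold (0 adjusted over the list alone, median -0.08, camera adjusted p = 0.0466, adjusted p = 0.718 with an estimated correlation). The propionate list fell likewise, 0 of 19 (3 adjusted over the list alone, median -0.13, camera adjusted p = 0.00863, adjusted p = 0.42 with an estimated correlation). Hspa5 did not pass with BCAA-free sham replicate 2 or 3 left out (adjusted p = 0.0908 and 0.0733). The ATF4 target list did not pass with BCAA-free TAC replicate 2 left out (camera adjusted p = 0.0746), nor did the BCAA catabolism list with BCAA-free sham replicate 3 or BCAA-free TAC replicate 1 (0.277 and 0.488). The propionate list did not pass with BCAA-free TAC replicate 1 left out (camera adjusted p = 0.0543).

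In sham hearts, collagen, interferon and macrophage genes were among those lower on the BCAA-free diet. Col3a1, a fibrillar collagen, fell from 5683 ± 619 to 2754 ± 350 normalised reads (log2 -1.05 ± 0.10, n = 3 per group, adjusted p = 0.00132), and Col15a1, a basement membrane collagen, fell too (-1.02 ± 0.09, adjusted p = 0.00132). The interferon-induced gene Ifit3 fell (-1.14 ± 0.15, adjusted p = 0.00396). Ptgds, which encodes a prostaglandin D synthase, rose from 12387 ± 2149 to 27750 ± 4807 normalised reads (1.16 ± 0.13, adjusted p = 0.00339). On GRCm38, Col3a1 (ENSMUSG00000026043, chromosome 1 from 45311538 to 45349706) and Ptgds (ENSMUSG00000015090, chromosome 2 from 25466709 to 25470046) are protein-coding genes. In all, 163 genes rose and 275 fell of 15596 tested, 28 and 40 of them at least 2-fold. The count of 438 was 362, 283 and 1019 without control sham replicates 1, 2 and 3, and 99, 68 and 88 without BCAA-free sham replicates 1, 2 and 3. With the replicate number as a block it was 713, 280 up and 433 down, with 424 shared. The genes named so far in this paragraph passed whichever library was left out.

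In the extracellular matrix list 1 rose and 17 fell of 41 (5 rose and 19 fell adjusted over the list alone, median -0.27, camera adjusted p = 6.12e-08, adjusted p = 0.394 with an estimated correlation), and Col1a1 was among those that fell (-0.68 ± 0.09, adjusted p = 0.00455). Fibroblast markers fell in 9 of 14 cases (10 adjusted over the list alone, median -0.44, camera adjusted p = 2.51e-11, adjusted p = 0.125 with an estimated correlation), led by the collagen VI genes Col6a1 (-0.52 ± 0.06) and Col6a2 (-0.71 ± 0.08). Interferon genes fell in 9 of 21 cases (16 adjusted over the list alone, median -0.68, camera adjusted p = 5.23e-14, adjusted p = 0.394 with an estimated correlation). Of the macrophage markers 5 of 22 fell (15 adjusted over the list alone, median -0.44, camera adjusted p = 4.21e-12, adjusted p = 0.0684 with an estimated correlation), including the complement genes C1qc (-0.52 ± 0.07) and C1qb (-0.61 ± 0.08). The cell cycle list fell with 3 of 24 past the threshold (6 adjusted over the list alone, median -0.50, camera adjusted p = 6.72e-06, adjusted p = 0.659 with an estimated correlation), Top2a, a DNA topoisomerase of dividing cells, among them (-1.54 ± 0.31, adjusted p = 0.0271). Top2a did not pass with control sham replicate 1 or 2 or any 1 BCAA-free sham library left out (adjusted p = 0.0661 to 0.12).

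BCAA catabolism genes did not pass as a list (median 0.06, camera adjusted p = 0.0658), but did with the replicate block (camera adjusted p = 0.0213). Bcat1, which starts BCAA breakdown, fell (-1.11 ± 0.25, adjusted p = 0.0418, and 0.0551 with the block). ATF4 targets (median -0.08, camera adjusted p = 0.477), propionate genes (median 0.07, camera adjusted p = 0.0768), fatty acid genes (median 0.02, camera adjusted p = 0.771) and respiratory chain genes (median 0.02, camera adjusted p = 0.511) did not pass. Lists that passed with the block alone were muscle atrophy and autophagy (camera adjusted p = 0.0227), endoplasmic reticulum stress (0.0438) and neutrophil markers (0.0348). Of the cardiac stress genes, Acta1 fell (-0.50 ± 0.10, adjusted p = 0.0292), while Nppa (0.64, adjusted p = 0.183), Nppb (0.13, adjusted p = 0.857) and Myh6 (0.03, adjusted p = 0.933) did not pass. Neither did Myh7 (0.28, adjusted p = 0.078), Atp2a2 (0.22, adjusted p = 0.285) and Postn (-0.50, adjusted p = 0.0692), which passed with the block (adjusted p = 0.0324, 0.0349 and 0.0359) and by DESeq2 (0.0123, 0.00658 and 0.00966). Bcat1 did not pass with control sham replicate 1 or 2 or any 1 BCAA-free sham library left out (adjusted p = 0.085 to 0.149), nor did Acta1 with control sham replicate 1 or 2 or BCAA-free sham replicate 2 or 3 (0.0598 to 0.129).

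Markers of other cell types also differed between sham groups. Adipocyte markers were higher on the BCAA-free diet in 3 of 7 cases (5 adjusted over the list alone, median 1.29, camera adjusted p = 1.59e-05, adjusted p = 0.394 with an estimated correlation). Examples were Retn, the hormone resistin (1.61 ± 0.29, adjusted p = 0.0174), and Cfd, the complement factor adipsin (1.03 ± 0.19, adjusted p = 0.0178). T cell markers were higher in 2 of 11 cases (9 adjusted over the list alone, median 1.60, camera adjusted p = 2.35e-08, adjusted p = 0.394 with an estimated correlation), including the receptor gene Trbc2 (1.60, adjusted p = 0.0157). Outside the list, Tcf7, a T cell transcription factor, rose (1.61 ± 0.26, adjusted p = 0.0103). Smooth muscle markers rose in 2 of 13 cases (4 rose and 1 fell adjusted over the list alone, median 0.07, camera adjusted p = 0.0229, adjusted p = 0.647 with an estimated correlation; 0.0534 by camera after quantile normalization), led by Myh11, the smooth muscle myosin (0.71 ± 0.09, adjusted p = 0.00396). Retn, Trbc2 and Tcf7 did not pass with any 1 BCAA-free sham library left out (adjusted p = 0.0569 to 0.0992), nor did Cfd with BCAA-free sham replicate 1 or 2 (0.0945 and 0.0911). The smooth muscle list did not pass with BCAA-free sham replicate 2 left out (camera adjusted p = 0.083).

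In TAC hearts, genes of cell division were far lower on the BCAA-free than on the control diet. Mki67 (ENSMUSG00000031004, chromosome 7 from 135689784 to 135716361, GRCm38) was at 961 ± 57.3 normalised reads in control TAC and 93.9 ± 63.5 in BCAA-free TAC, an 11.2-fold fall (log2 -3.48 ± 0.35, n = 3 per group, adjusted p = 0.00305). Top2a (ENSMUSG00000020914, chromosome 11 from 98992943 to 99024189) fell 9.04-fold (-3.18 ± 0.33, adjusted p = 0.00307). Pbk, a mitotic kinase gene, fell 10.8-fold (-3.44 ± 0.33, adjusted p = 0.00302) and Pclaf, which binds the DNA clamp at replication forks, changed by -3.13 ± 0.38. Of the cell cycle list, 23 of 26 fell (25 adjusted over the list alone, median -2.09, camera adjusted p = 1.34e-31, adjusted p = 0.434 with an estimated correlation). Among them were Cdk1, the kinase that starts mitosis (-3.02 ± 0.29, adjusted p = 0.00302), and Cdc20, which activates the exit from it (-2.06 ± 0.20, adjusted p = 0.00302). These 6 genes passed whichever library was left out.

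**Figure D2:**
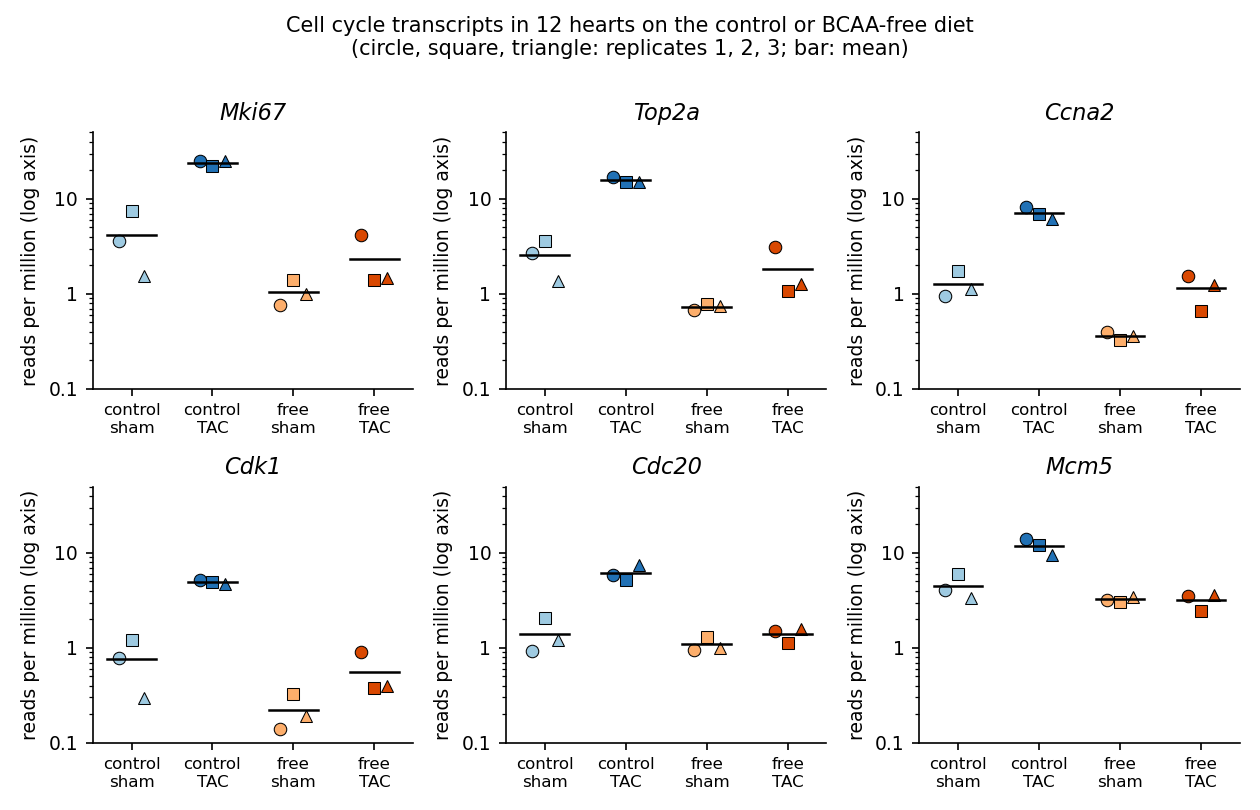
Level in CPM (logarithmic axis) of cell cycle genes in the 12 libraries, with 1 point per library and a bar at each group mean. Mki67 was at 24.1 ± 1.51 CPM in control TAC hearts, 2.35 ± 1.59 in BCAA-free TAC, 4.16 ± 2.96 in control sham and 1.05 ± 0.329 in BCAA-free sham (SD, n = 3).

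The 3 control TAC libraries serve this comparison and TAC on the control diet, so their chance values enter both. Each other group likewise serves a diet and a TAC comparison, so the same holds for its libraries. In all, 206 genes rose and 342 fell of 16222 tested, 10 and 174 of them at least 2-fold. The count of 548 was 334, 139 and 100 without control TAC replicates 1, 2 and 3, and 1044, 177 and 285 without BCAA-free TAC replicates 1, 2 and 3. Without both control TAC replicates 2 and 3, limma called 0 genes (1750 at an unadjusted p under 0.05), edgeR called 11, and the cell cycle list had 0 of 26 members past the threshold at a median of -2.09 (camera adjusted p = 1e-22). The extracellular matrix list did not pass with all libraries (median 0.03, camera adjusted p = 0.886), nor did the macrophage list (median 0.01, camera adjusted p = 0.62). Without the same 2 libraries, where only control TAC replicate 1 remains, both were lower on the BCAA-free diet, with medians of -0.63 (camera adjusted p = 1.14e-05) and -0.37 (0.000108). Without BCAA-free TAC replicate 1 the extracellular matrix list was lower as well (median -0.32, camera adjusted p = 0.00073). Without control TAC replicate 1 both passed as higher (medians 0.34 and 0.25).

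The ATF4 target Mthfd2 fell (-1.97 ± 0.20, adjusted p = 0.00307), while in its list 1 rose and 4 fell of 30, which did not pass (1 rose and 7 fell adjusted over the list alone, median -0.05, camera adjusted p = 0.15). Respiratory chain genes were higher on the BCAA-free diet in 10 of 46 cases (21 adjusted over the list alone, median 0.22, camera adjusted p = 3.91e-14, adjusted p = 0.746 with an estimated correlation), for example Cox6c (0.62 ± 0.10, adjusted p = 0.0141). Ribosomal protein genes were higher in 9 of 37 cases (20 adjusted over the list alone, median 0.19, camera adjusted p = 1.26e-12, adjusted p = 0.746 with an estimated correlation), led by Rpl37 (0.63 ± 0.08, adjusted p = 0.00545). BCAA catabolism genes were higher as a list, 1 of 22 past the threshold (2 adjusted over the list alone, median 0.14, camera adjusted p = 0.00284, adjusted p = 0.77 with an estimated correlation), which was Acadsb, of isoleucine breakdown (0.36, adjusted p = 0.0277). The fatty acid list was higher with 0 of 34 past the threshold (0 adjusted over the list alone, median 0.14, camera adjusted p = 6.25e-05, adjusted p = 0.77 with an estimated correlation). After quantile normalization the camera adjusted p was 0.054 for BCAA catabolism and 0.128 for fatty acids. Cox6c did not pass with control TAC replicate 2 or 3 or BCAA-free TAC replicate 2 or 3 left out (adjusted p = 0.0565 to 0.0828), nor did Acadsb with any 1 control TAC library or BCAA-free TAC replicate 2 or 3 (0.0787 to 0.123). The BCAA catabolism list did not pass with control TAC replicate 1 left out (camera adjusted p = 0.0555).

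Interferon genes were lower in 5 of 21 cases (16 adjusted over the list alone, median -0.46, camera adjusted p = 3.13e-09, adjusted p = 0.694 with an estimated correlation), including Bst2, which tethers virus particles (-0.62 ± 0.09, adjusted p = 0.00852). Among cardiac stress genes Myh7 was higher (0.77 ± 0.14, adjusted p = 0.0214, and 0.093 after quantile normalization). Nppa (1.28, adjusted p = 0.138), Nppb (-0.30, adjusted p = 0.614), Acta1 (-1.27, adjusted p = 0.118), Myh6 (0.13, adjusted p = 0.796), Atp2a2 (0.17, adjusted p = 0.595), Col1a1 (-0.28, adjusted p = 0.771) and Postn (-0.06, adjusted p = 0.963) did not pass. Ptgds was higher (1.14 ± 0.18, adjusted p = 0.0116). Adipocyte markers were higher with 0 of 8 past the threshold (2 adjusted over the list alone, median 1.14, camera adjusted p = 0.00284, adjusted p = 0.77 with an estimated correlation). Neutrophil markers were higher with 0 of 5 (3 adjusted over the list alone, median 1.41, camera adjusted p = 0.00571, adjusted p = 0.746 with an estimated correlation). Neither list was called with control TAC replicates 2 and 3 both left out (medians 0.32 and 0.32, camera adjusted p = 0.377 and 0.34). Fast skeletal muscle markers were higher with 1 of 6 past the threshold (4 adjusted over the list alone, median 0.83, camera adjusted p = 0.00264, adjusted p = 0.434 with an estimated correlation), Mylpf, a myosin light chain (1.10, adjusted p = 0.0374). Bst2 did not pass with control TAC replicate 2 or 3 left out (adjusted p = 0.0506 and 0.0806), nor did Myh7 with control TAC replicate 2 or 3 or BCAA-free TAC replicate 2 or 3 (0.0552 to 0.155). Ptgds did not pass with control TAC replicate 2 or BCAA-free TAC replicate 2 left out (adjusted p = 0.067 and 0.0725), nor did Mylpf with any 1 control TAC library or BCAA-free TAC replicate 2 or 3 (0.0734 to 0.173).

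Whether the TAC response itself differed between diets was tested as the response on the BCAA-free diet minus that on the control diet. Klf2, a transcription factor of endothelial and T cells, went from 1602 ± 195 to 2532 ± 111 normalised reads with TAC on the control diet and from 3690 ± 435 to 2511 ± 214 on the BCAA-free diet, a difference of -1.22 ± 0.14 (n = 3 per group, adjusted p = 0.00401). Lmnb1, a protein of the nuclear lamina, went from 220 ± 14.4 to 550 ± 24.5 on the control diet and from 205 ± 5.28 to 221 ± 4.78 on the BCAA-free diet (-1.20 ± 0.14, adjusted p = 0.00401). On GRCm38, Klf2 (ENSMUSG00000055148, chromosome 8 from 72319033 to 72321656) and Lmnb1 (ENSMUSG00000024590, chromosome 18 from 56707813 to 56753424) are protein-coding genes. In all 7 of 15524 genes passed, 1 with a more positive and 6 with a more negative TAC difference on the BCAA-free diet. At an unadjusted p under 0.05 there were 1568, edgeR called 5, and DESeq2 called 109, of which 41 were up and 68 down. The others of the 7 were Stmn1, which destabilises microtubules (-1.08 ± 0.17, adjusted p = 0.0433), the splicing factor gene Srsf2 (-0.64 ± 0.09, adjusted p = 0.0404), Igfbp6, which binds insulin-like growth factor II (0.79 ± 0.12, adjusted p = 0.0404), and, chosen after their values were seen, Cdc7 (-1.98) and Gm25262 (-2.54). Klf2 and Lmnb1 passed whichever of the 12 libraries was left out. Stmn1 and Igfbp6 passed in 2 and Srsf2 in 4 of these 12 fits, with adjusted p-values up to 0.164, 0.144 and 0.14. Stmn1 also missed the threshold with a pseudocount of 1 (adjusted p = 0.0511), after quantile normalization (0.0549) and by edgeR (0.0528). The count of 7 was 11, 3 and 2 without control sham replicates 1, 2 and 3, 2, 3 and 2 without the control TAC replicates, 2, 2 and 2 without the BCAA-free sham replicates and 15, 2 and 5 without the BCAA-free TAC replicates, in the same order. Without both control TAC replicates 2 and 3 it was 1 (1510 at an unadjusted p under 0.05, and 1 by edgeR), and 0 of the 7 were called.

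As a list, cell cycle genes had a smaller TAC response on the BCAA-free diet (median -1.28, camera adjusted p = 8.05e-22, adjusted p = 0.332 with an estimated correlation), with 0 members past the threshold over all genes and 20 of 25 adjusted over the list alone. Respiratory chain genes differed the other way (median 0.21, camera adjusted p = 1.4e-13, adjusted p = 0.703 with an estimated correlation), with 0 past the threshold and 0 of 46 adjusted over the list alone. So did macrophage markers (median 0.51, camera adjusted p = 1.2e-07, adjusted p = 0.636 with an estimated correlation), with 0 and 7 of 22 adjusted over the list alone, and fibroblast markers (median 0.39, camera adjusted p = 1.95e-07, adjusted p = 0.332 with an estimated correlation), with 0 and 6 of 14 adjusted over the list alone. The macrophage list was not called with control TAC replicates 2 and 3 both left out (median -0.04, camera adjusted p = 0.502). Of the cardiac stress genes, Nppa (0.63, adjusted p = 0.775), Myh7 (0.49, adjusted p = 0.328), Acta1 (-0.77, adjusted p = 0.615) and Postn (0.43, adjusted p = 0.87) did not pass.

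The size of the TAC response was compared over the 2633 genes past the threshold for the mean TAC effect, of which 1501 rose and 1132 fell. The change was smaller on the BCAA-free diet for 1410 of them, or 53.6% (95% exact binomial interval 51.6 to 55.5), with 51.3% of those that rose and 56.5% of those that fell. The sign was the same on both diets for 2606. The median absolute log2 change of these genes was 0.37 on the control and 0.33 on the BCAA-free diet. The percent was 45.6 without control TAC replicate 1, 49.5 without BCAA-free sham replicate 3 and 42.7 without BCAA-free TAC replicate 3, below 50 in each case, so no direction is given.

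**Figure D3:**
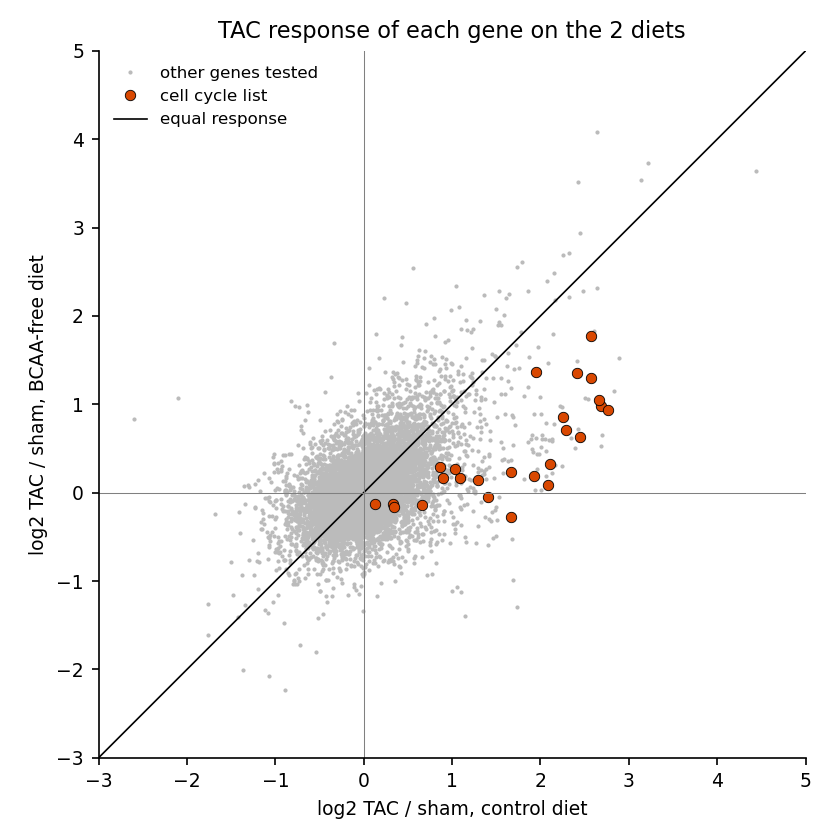
Log2 TAC change on the control diet (horizontal axis) and on the BCAA-free diet (vertical axis), with 1 point per gene of the 15524 tested, cell cycle genes in colour and a line at equal change. The cell cycle genes had a median difference of -1.28.

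Averaged over surgery, cell cycle, interferon and endothelial genes were among those lower on the BCAA-free diet, and adipose, ribosomal and autophagy genes among those higher. Uhrf1, which maintains DNA methylation at replication, fell (log2 -2.15 ± 0.20, n = 3 per group, adjusted p = 0.000253), and so did Ccna2 (-2.05 ± 0.20, adjusted p = 0.000287), Top2a (-2.36 ± 0.25), Mki67 (-2.56 ± 0.32) and Ifit3 (-0.88 ± 0.11, adjusted p = 0.00049). Ptgds (1.15 ± 0.12, adjusted p = 0.000394) and Retn (1.79 ± 0.30, adjusted p = 0.00284) rose. In all, 803 genes rose and 1016 fell of 15458 tested, 26 and 96 of them at least 2-fold. The count of 1819 was 1424, 1094 and 2035 without control sham replicates 1, 2 and 3, 1568, 1249 and 1414 without the control TAC replicates, 1062, 1449 and 1067 without the BCAA-free sham replicates and 2484, 1079 and 1559 without the BCAA-free TAC replicates, in the same order. Without both control TAC replicates 2 and 3 it was 850 (3586 at an unadjusted p under 0.05, and 904 by edgeR), with 718 shared.

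Cell cycle genes fell in 21 of 24 cases (23 adjusted over the list alone, median -1.15, camera adjusted p = 4.48e-23, adjusted p = 0.299 with an estimated correlation). Interferon genes fell in 15 of 21 (18 adjusted over the list alone, median -0.57, camera adjusted p = 1.76e-13, adjusted p = 0.299 with an estimated correlation), Gbp3, a guanylate-binding protein, among them (-0.86, adjusted p = 0.00166). Endothelial markers fell in 4 of 14 cases (4 adjusted over the list alone, median -0.14, camera adjusted p = 0.00527, adjusted p = 0.588 with an estimated correlation), including the transcription factor gene Erg (-0.46, adjusted p = 0.00298), and did not pass without both control TAC replicates 2 and 3 (camera adjusted p = 0.112). Adipocyte markers rose in 3 of 7 cases (6 adjusted over the list alone, median 1.18, camera adjusted p = 0.0006, adjusted p = 0.588 with an estimated correlation). Ribosomal protein genes rose in 19 of 37 cases (28 adjusted over the list alone, median 0.15, camera adjusted p = 8.29e-12, adjusted p = 0.588 with an estimated correlation). Muscle atrophy and autophagy genes rose in 5 of 16 cases (6 adjusted over the list alone, median 0.12, camera adjusted p = 0.00471, adjusted p = 0.299 with an estimated correlation), including Map1lc3b of the autophagosome membrane (0.27, adjusted p = 0.00294) and Cdkn1a, an inhibitor of cell division (0.45, adjusted p = 0.00398). Cdkn1a (adjusted p = 0.0502) did not pass with control TAC replicates 2 and 3 both left out.

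In BCAA catabolism 6 rose and 1 fell of 22 (7 rose and 1 fell adjusted over the list alone, median 0.10, camera adjusted p = 0.00557, adjusted p = 0.717 with an estimated correlation), with Acadsb up (0.35 ± 0.06, adjusted p = 0.00248) and Bcat1 down (-0.91 ± 0.17, adjusted p = 0.0049). The propionate list rose, 3 of 19 past the threshold (3 adjusted over the list alone, median 0.09, camera adjusted p = 0.0125, adjusted p = 0.602 with an estimated correlation). Respiratory chain genes rose in 8 of 46 cases (14 adjusted over the list alone, median 0.12, camera adjusted p = 5.19e-08, adjusted p = 0.693 with an estimated correlation). The ATF4 targets Mthfd2 (-1.33 ± 0.22, adjusted p = 0.00277) and Aldh1l2 (-0.84 ± 0.15, adjusted p = 0.00431), both of mitochondrial folate metabolism, fell, while their list did not pass (median -0.02, camera adjusted p = 0.216). Myh7 rose (0.53 ± 0.08, adjusted p = 0.00234) and Acta1 fell (-0.89 ± 0.23, adjusted p = 0.0236). In the extracellular matrix list 0 rose and 5 fell of 41, which did not pass (1 rose and 6 fell adjusted over the list alone, median -0.11, camera adjusted p = 0.163) but did without both control TAC replicates 2 and 3 (median -0.36, camera adjusted p = 1.02e-07). Acta1 did not pass by edgeR (adjusted p = 0.0523) or DESeq2 (0.0927). Acta1 did not pass with control sham replicate 2 or BCAA-free sham replicate 3 or BCAA-free TAC replicate 2 left out (adjusted p = 0.0528 to 0.0666). Aldh1l2 (adjusted p = 0.0506) and Acta1 (adjusted p = 0.077) did not pass with control TAC replicates 2 and 3 both left out. The propionate list did not pass with control TAC replicate 1 left out (camera adjusted p = 0.0522).

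**Figure D4:**
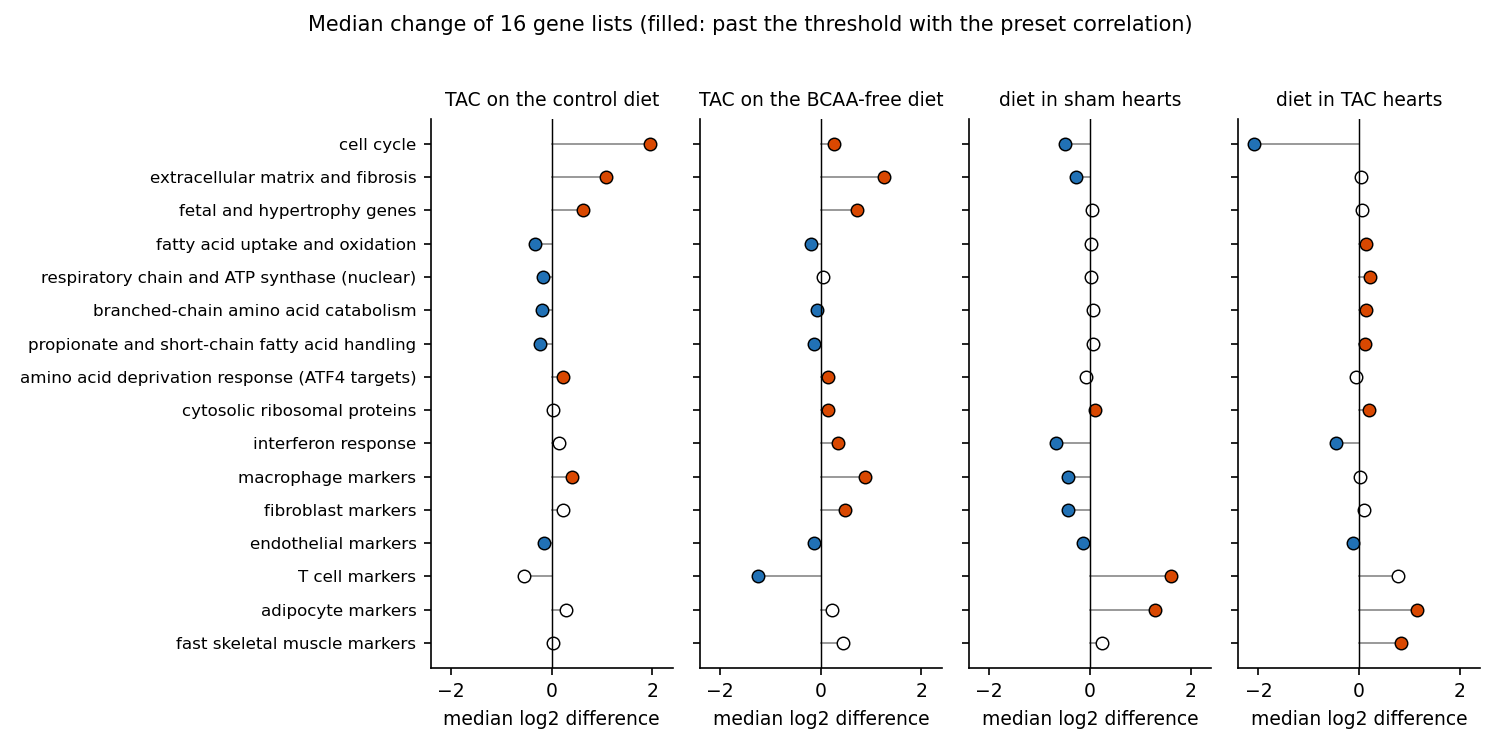
Median log2 difference (horizontal axes) of 16 gene lists in the 4 pairwise comparisons, with filled points where the list passed camera at the preset correlation of 0.01. The cell cycle list lay at 1.94 for TAC on the control diet and at -2.09 for diet in TAC hearts, and the interferon list at -0.68 and -0.46 for diet in sham and in TAC hearts.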

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

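The test of macrophage markers and the fits without both control TAC replicates 2 and 3 were chosen only after the result was seen. The test of the difference between both TAC responses picked out 5 of the named genes and 13 lists. On the log2 scale, as the response on the BCAA-free minus that on the control diet, Igfbp6 differed by 0.788, Klf2 by -1.22, Lmnb1 by -1.2, Stmn1 by -1.08 and Srsf2 by -0.635, with limma adjusted p-values of 0.00401 to 0.0433. Klf2 and Lmnb1 passed with each of the 12 libraries left out, while Igfbp6, Stmn1 and Srsf2 did not. Among 100 regroupings of the 12 libraries, 9 including the real one called at least 7 genes, with up to 3561 in another. The regrouping with 3561 exchanged the diet labels within 1 surgery. This turns the diet effect common to both surgeries, and any offset between the separately normalized tables, into a difference of responses. Other regroupings may carry part of both, which were not tested apart, so these shares cannot decide on chance.

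The median difference of the cell cycle list was -1.28, of the respiratory chain 0.213, of macrophage markers 0.505 and of fibroblast markers 0.385. Their camera adjusted p with an estimated correlation was 0.332 to 0.703. Further lists with a more positive TAC response on the BCAA-free diet were the extracellular matrix at 0.282 (camera adjusted p = 0.0169), fatty acid oxidation at 0.155 (6.3e-05), the TCA cycle at 0.119 (0.00581), glycolysis at 0.123 (0.014), ribosomal proteins at 0.0691 (8.6e-06), interferon response at 0.237 (0.0181), neutrophil markers at 2.04 (0.000239) and fast skeletal muscle markers at 0.562 (0.014). The endoplasmic reticulum stress list stood at -0.119 (camera adjusted p = 0.0305). No member of these 9 lists was among the genes called over all genes, 5 ribosomal and 4 neutrophil genes rose adjusted over the list alone, and the lists had adjusted p = 0.332 to 0.898 with an estimated correlation. The extracellular matrix list did not pass with control sham replicate 2 or control TAC replicate 2 or 3 or BCAA-free sham replicate 1 left out (camera adjusted p = 0.0638 to 0.522), nor did the TCA cycle list with control TAC replicate 1 (0.178). The glycolysis list did not pass with control sham replicate 1 or BCAA-free TAC replicate 2 left out (camera adjusted p = 0.0693 and 0.0543), nor did the endoplasmic reticulum stress list with control sham replicate 1 or 2 or control TAC replicate 1 or 2 or BCAA-free sham replicate 2 or BCAA-free TAC replicate 2 (0.0576 to 0.377). The interferon list did not pass with control sham replicate 2 or 3 or control TAC replicate 1 or BCAA-free TAC replicate 1 or 3 left out (camera adjusted p = 0.0532 to 0.621), nor did the fast skeletal muscle list with BCAA-free sham replicate 2 (0.0618). Without BCAA-free TAC replicate 1 the extracellular matrix list turned to -0.13 (camera adjusted p = 0.517), and without both control TAC replicates 2 and 3 it passed at -0.28 (0.00261). After quantile normalization camera did not call the TCA cycle (0.798), glycolysis (0.611) or ribosomal (0.0539) lists. Of the 100 regroupings, 43 called at least 13 lists, with up to 20 in another. In 18 the cell cycle median was at least 1.28 from 0, with up to 2.27. These too cannot decide on chance.

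The pattern weighed is that of the cell cycle list, with a median of -2.09 for diet in TAC hearts. The liver RNA of control TAC replicate 3 and the non-coding RNA of control TAC replicate 2 are argued against as its cause, since the median was -2.04 without the former, -2.16 without the latter and -2.09 without both. Fewer macrophages of every kind, with cell cycle genes in constant proportion to them, are argued against by a macrophage median of 0.011 (interquartile range 0.308), which was -0.37 without both libraries. A lower number of dividing cells of some type on the BCAA-free diet may account for it, a hypothesis that whole hearts leave untested, as they do a change in the cells that divide. Counts of cycling cells by type would test it.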

How the results depend on the processing

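The fits without both control TAC replicates 2 and 3 were chosen only after the data were seen. Counts are given in the order TAC on the control diet, TAC on the BCAA-free diet, diet in sham hearts, diet in TAC hearts, difference of TAC responses and averaged diet effect, where the main counts were 848, 688, 438, 548, 7 and 1819 genes and 15, 20, 15, 14, 13 and 16 lists. A pseudocount of 16, no filter and edgeR kept every gene count within 1.5 times the main one; so did a pseudocount of 1, a mean of at least 50 and quantile normalization, except for the difference of responses, with 4 genes under each of the 3. DESeq2 called 1544, 1159, 826, 1181, 109 and 2383, of which the averaged count lay within 1.5 times. The authors' deposited table called 1548, 1145, 813 and 1188 in the pairwise comparisons, with 845, 683, 434 and 542 shared. One edgeR fit of all 12 libraries called 1159, 730, 155 and 1202. The cause of these differences was not tested. In the difference of responses 1 of 7 calls was positive (14.3%), 1 of 4 after quantile normalization (25%) and 41 of 109 by DESeq2 (37.6%).

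With the replicate number as a block 805, 525, 713, 1275, 3 and 1831 genes and 18, 21, 19, 16, 14 and 16 lists were called. In the difference of responses this ended the calls of Stmn1 (adjusted p = 0.0779) and Igfbp6 (0.107). For diet in TAC hearts 2 of 3 pairs of equal number correlated above 0.1 (0.00312 to 0.391), with TAC on the control diet at -0.128 to 0.0863 and on the BCAA-free diet at -0.174 to 0.0476. Not every library correlated best with its own number: 2, 1, 4 and 4 of 6 did in the pairwise comparisons. Of named genes, 11 of 54, 16 of 56, 12 of 44, 8 of 29, 2 of 5 and 46 of 62 that passed did so whichever library was left out, and of lists 12 of 15, 14 of 20, 8 of 15, 9 of 14, 7 of 13 and 11 of 16. With 1 library left out, gene counts were 91 to 660, 105 to 1195, 68 to 1019 and 100 to 1044 in the pairwise comparisons. They were 2 to 15 for the difference of responses and 1062 to 2484 for the averaged effect. List counts ranged over 14 to 19, 17 to 23, 13 to 19, 12 to 15, 10 to 17 and 14 to 19. Fewer libraries lower the power to call a gene; why counts rose without others was not tested. The percent of genes with a smaller TAC response on the BCAA-free diet ranged from 42.7 (without BCAA-free TAC replicate 3) to 63.4 (control TAC replicate 3).

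With control TAC replicates 2 and 3 both left out, limma called 180 genes for TAC on the control diet, 0 for diet in TAC hearts (1750 at an unadjusted p under 0.05, 11 by edgeR), 1 for the difference of responses and 850 for the averaged effect, where 1 control TAC library remains, with 18, 13, 19 and 17 lists. For diet in TAC hearts the extracellular matrix median turned, with camera's adjusted p in parentheses, to -0.63 (1.14e-05), and to -0.32 (0.00073) without BCAA-free TAC replicate 1 (up to 0.34 without control TAC replicate 1), the macrophage median to -0.37 (0.000108) and the mesothelial median to -0.81 (0.0116). For the difference of responses the extracellular matrix turned to -0.28 (0.00261), and to -0.13 (0.517) without BCAA-free TAC replicate 1 (up to 0.52 without control TAC replicate 1), and the fetal and hypertrophy list to -0.37 (0.0126). Red blood cell markers for TAC on the BCAA-free diet turned to 0.36 (0.00348) without BCAA-free TAC replicate 1, from a lowest -0.21 without BCAA-free TAC replicate 3. The TCA cycle list in TAC hearts was called with a median of 0.13 and had one of 0.00178 with a negative test direction after quantile normalization (camera adjusted p = 0.893). The cause was not tested.

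With an estimated correlation camera called 0, 0, 0, 0, 0 and 0 lists (3, 3, 2, 2, 4 and 5 at an unadjusted p under 0.05), a setting that also lowers its degrees of freedom. The test fry called 2, 1, 2, 2, 0 and 6 (9, 15, 10, 8, 5 and 14 at an unadjusted p under 0.05). Quantile normalization gave 17, 21, 12, 10, 10 and 16 lists. Of 394 values of named genes, DESeq2 ended 5 calls and added 43, edgeR ended 13 and added 2, quantile normalization ended 18 and added 1, the block ended 19 and added 27, and pseudocounts of 1 and 16 ended 4 and 5 and added 0 and 1. Of 234 list values quantile normalization ended 11 calls, added 5 and turned 1, the block ended 0 and added 11, and a pseudocount of 1 ended 0 and added 1. Leaving out 1 library ended 609 and added 38 of 3114 gene values and ended 65, added 89 and turned 3 of 1872 list values. Leaving out both doubted libraries ended 90 and added 1 of 257 gene values and ended 7, added 12 and turned 5 of 156 list values. Turned lists changed test direction, passed in at least 1 of the 2 fits and are not among those ended or added. No named gene that passed changed sign in these fits. Genes with a mean under 10 were left out as too shallow.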

Other observations

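The tests of liver RNA, blood and ribosomal RNA were chosen only after the result was seen. Single genes of the circadian clock changed in both directions, although the clock list passed in no comparison. Arntl, a transcription factor of the clock's positive arm, fell with TAC on the control diet (-1.76 ± 0.40, adjusted p = 0.0379) and on the BCAA-free diet (-1.25 ± 0.19, adjusted p = 0.00802). Ciart, a repressor of the clock, rose with TAC on the BCAA-free diet (1.22 ± 0.14, adjusted p = 0.00285). On the BCAA-free diet Arntl was higher in TAC hearts (1.80 ± 0.24, adjusted p = 0.00643) and in the average (1.54 ± 0.25, adjusted p = 0.00248). In the list 0 rose and 2 fell of 17 with TAC on the control diet, and 4 and 3 on the BCAA-free diet, 2 and 3 with diet in sham and 1 and 0 in TAC hearts (camera adjusted p = 0.159 to 0.685 over all comparisons). For TAC on the control diet, Arntl did not pass with control sham replicate 2 or any 1 control TAC library left out (adjusted p = 0.0517 to 0.126). For TAC on the BCAA-free diet, Arntl did not pass with BCAA-free sham replicate 1 or 2 left out (adjusted p = 0.0561 and 0.0582). For diet in TAC hearts, Arntl did not pass with control TAC replicate 3 left out (adjusted p = 0.0539). With control TAC replicates 2 and 3 both left out, Arntl did not pass for TAC on the control diet (adjusted p = 0.261) or diet in TAC hearts (0.328). The time of day of sampling is not given in the sources used here.

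Further lists moved with surgery by camera, whose adjusted p-values are given for lists from here on. On the control diet ion channel genes (0 of 16 fell, 1 rose and 5 fell adjusted over the list alone, median -0.16, adjusted p = 0.0119) and endothelial markers (1 of 14 fell, 4 adjusted over the list alone, median -0.15, adjusted p = 0.00266) were lower after TAC. Immediate early genes (2 of 18 rose, 3 adjusted over the list alone, median 0.42, adjusted p = 0.00978) and mesothelial markers (0 of 8 rose, 0 adjusted over the list alone, median 1.13, adjusted p = 0.0184) were higher, and these 4 lists had adjusted p = 0.487 to 0.723 with an estimated correlation. The endothelial list did not pass with control sham replicate 2 left out (camera adjusted p = 0.12), nor did the immediate early gene list with control sham replicate 3 or control TAC replicate 1 or 2 (0.0537 to 0.182). The mesothelial list did not pass with control TAC replicate 1 left out (camera adjusted p = 0.161). On the BCAA-free diet metabolic regulators (1 of 16 fell, 3 adjusted over the list alone, median -0.15, adjusted p = 0.00521) and endothelial markers (2 of 14 fell, 5 adjusted over the list alone, median -0.15, adjusted p = 0.000336) were lower. Glycolysis (1 of 22 rose, 7 adjusted over the list alone, median 0.18, adjusted p = 0.00248) and immediate early (3 of 18 rose, 6 adjusted over the list alone, median 0.35, adjusted p = 0.00878) genes were higher. So were glucocorticoid response (4 of 14 rose, 6 adjusted over the list alone, median 0.16, adjusted p = 0.0159) and mesothelial (1 of 9 rose, 4 adjusted over the list alone, median 1.07, adjusted p = 0.00842) genes, all with adjusted p = 0.411 with an estimated correlation. The immediate early gene list did not pass with BCAA-free sham replicate 3 or BCAA-free TAC replicate 2 left out (camera adjusted p = 0.0604 and 0.053), nor did the glucocorticoid response list with BCAA-free sham replicate 3 or BCAA-free TAC replicate 2 or 3 (0.0593 to 0.0713).

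With diet in sham hearts, ribosomal genes (0 of 37 rose, 0 adjusted over the list alone, median 0.09, adjusted p = 0.000122) and atrial markers (0 of 9 rose, 2 adjusted over the list alone, median 0.50, adjusted p = 0.00342) were higher on the BCAA-free diet. Glycolysis (3 of 22 fell, 3 rose and 5 fell adjusted over the list alone, median -0.10, adjusted p = 0.0169), heat shock (1 of 14 fell, 1 adjusted over the list alone, median -0.12, adjusted p = 0.0174) and endothelial (1 of 14 fell, 4 adjusted over the list alone, median -0.15, adjusted p = 0.00244) genes were lower. These 5 lists had adjusted p = 0.659 to 0.666 with an estimated correlation. The atrial list did not pass with control sham replicate 1 left out (camera adjusted p = 0.0722), nor did the glycolysis list with control sham replicate 1 or BCAA-free sham replicate 2 (0.125 and 0.0664). The heat shock list did not pass with control sham replicate 3 or BCAA-free sham replicate 3 left out (camera adjusted p = 0.441 and 0.0656), nor did the endothelial list with control sham replicate 2 (0.0511). In TAC hearts muscle atrophy and autophagy genes (3 of 16 rose, 5 adjusted over the list alone, median 0.18, adjusted p = 0.00284) and atrial markers (0 of 9 rose, 5 adjusted over the list alone, median 0.38, adjusted p = 0.00696) were higher and endothelial markers (1 of 14 fell, 1 rose and 4 fell adjusted over the list alone, median -0.12, adjusted p = 0.0211) lower, with adjusted p = 0.694 to 0.77 with an estimated correlation. The atrial list did not pass with control TAC replicate 3 left out (camera adjusted p = 0.167), nor did the endothelial list with control TAC replicate 3 or BCAA-free TAC replicate 1 (0.152 and 0.0647). The atrial and endothelial lists also did not pass without both control TAC replicates 2 and 3 (0.299 and 0.56).

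Averaged over surgery, T cell (1 of 10 rose, 9 adjusted over the list alone, median 1.16, adjusted p = 0.00137), atrial (1 of 9 rose, 6 adjusted over the list alone, median 0.49, adjusted p = 0.00527) and fast skeletal muscle (2 of 6 rose, 3 adjusted over the list alone, median 0.62, adjusted p = 0.0128) markers were higher on the BCAA-free diet. Macrophage (1 of 22 fell, 0 adjusted over the list alone, median -0.26, adjusted p = 0.0061) and fibroblast (6 of 14 fell, 2 rose and 7 fell adjusted over the list alone, median -0.25, adjusted p = 0.0128) markers were lower, among them Ddr2, a collagen receptor (-0.31 ± 0.06, adjusted p = 0.0049). The 5 lists had adjusted p = 0.299 to 0.717 with an estimated correlation. The macrophage list and the fibroblast list did not pass with control TAC replicate 1 left out (camera adjusted p = 0.222 and 0.0522). Some lists passed (adjusted p = 0.00583 to 0.0461) but neither after quantile normalization (0.0534 to 0.893) nor with an estimated correlation (0.299 to 0.874). These were ion channels and immediate early genes in sham hearts, propionate and TCA cycle genes in TAC hearts, and ion channels and fatty acids in the average. Apart from the clock, 9 lists passed in no comparison, with lowest camera adjusted p-values of 0.0841 for adult contractile and calcium handling genes, 0.128 for aminoacyl-tRNA synthetases, 0.122 for mitochondrially encoded mRNAs, 0.184 for cholesterol synthesis, 0.603 for fatty acid synthesis, 0.159 for histone acyltransferases and deacylases, 0.397 for B cell markers, 0.237 for red blood cell markers and 0.15 for nerve and Schwann cell markers.

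Control TAC replicate 3 held liver transcripts, with 33 of the 34 markers (97.1%) highest in that library of those in which they were listed, the exception being Hp. It had 6668 reads of Alb, 1172 of Cyp3a11 and 1080 of Mup3, while 7 of the 34 genes were also listed in BCAA-free sham hearts. Blood left in the sample is argued against by red blood cell markers, whose median log2 ratio to the other control TAC libraries was -0.049 (interquartile range 0.241, 9 genes). RNA or reads of liver remain a candidate source, and whether they entered at dissection, in the library or in sequencing was not tested. No biological explanation was tested, as 1 library of a group shows it.

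Control TAC replicate 2 held more non-coding RNA, with 2.48% of its reads on transcripts linked to ribosomal RNA against 0.179% to 0.675% in the other 11 libraries. Carry-over of cytoplasmic ribosomal RNA alone is argued against by Rn7sk, Rmrp and Rpph1, whose median log2 ratio to the other control TAC libraries was 5.62 (interquartile range 0.38, 3 genes). Less complete selection of polyadenylated RNA may account for both, but cannot be told apart from other sources, since histone mRNAs, most of which lack a poly(A) tail, had a median log2 ratio of 0.398 within an interquartile range of 0.606 over 15 genes. No biological explanation was tested.

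The 10 splits of the 6 libraries of a pairwise comparison are too few for a share under 0.05. The real split called 848 genes for TAC on the control diet against at most 1 in the others, 688 against 0 on the BCAA-free diet, 438 against 0 for diet in sham and 548 against 0 in TAC hearts, which is 1 of 10 each. Lists called numbered 15 against at most 21 (5 of 10 as many), 20 against 20 (2 of 10), 15 against 16 (4 of 10) and 14 against 22 (6 of 10). Among the 4 sham splits that part all 3 pairs, the real one called 438 genes and the others 0; the other 6 splits part 1 pair. For the averaged diet effect 100 regroupings were drawn. The real one alone reached 1819 genes (1 of 100), with up to 770 in another. Chance between these libraries was thus made unlikely but not excluded, as among the 35 that part all 3 sham pairs (1, up to 44). These are the smallest shares that such draws can give. Chance between mice was not tested, since the labels do not say that libraries came from separate mice. The cell cycle median of -1.15 was reached in size by 2 of 100 and by 2 of the 35 (up to 1.16). Among the 35 this does not exclude chance. For its 16 lists chance was not excluded (16 of 100, up to 21 in another).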
